A study of Homo sapiens with 4 samples.

How the data were processed

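Total RNA of 4 cultures of 2 established breast cancer cell lines was labelled with biotin and hybridised to Affymetrix arrays, 1 array per line and medium, per the labels' protocols. The deposited table holds log2 expression values, 1 per probe set and array, without gene names. Per the submitters' processing notes the authors used RMA (robust multi-array average), a method that corrects background, equalises the arrays' distributions and combines the probes of a probe set; its version, software and background option, and which arrays were processed together, are not given in the sources used here. The log base is not stated. The values run from 0.727 to 13.7, and values that high on a natural or decimal log scale would exceed the range of an array scanner, so they were read as log2. The array means agreed closely while quartiles and medians differed slightly, and no detection call accompanies the values. Values near the lower end have no background measured per probe set, so a fold change against such a value depends on where the processing sets that end. Equalising the distributions also removes any overall difference in signal between the arrays.

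Groups were taken from the sample titles. Parental lines were not analysed here, so no value is a difference from untreated cells, and the ODTR and TR cultures differ in serum, phenol red and the total time in culture together. The 62 control probe sets were set aside, with some of them reported separately and others not reported here, and of the other 54613, those whose mean over the 4 arrays reached the median of all probe sets (2.76) were kept, which left 27307. Within a line, the log2 difference between ODTR and TR was taken, with a difference of 1 (2-fold) as the threshold and no p-value; probe sets past it are called changed as a description of size. The medium effect common to both lines and the cell line difference common to both media were fitted to the 4 arrays with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided), with cell line and medium as additive terms and 1 residual degree of freedom, and adjusted by Benjamini-Hochberg with a threshold of 0.05. Each line was grown in both media, so the line pairs the arrays by design. The residual of this fit is the difference between the lines in their response, and the estimated prior had 4.69 degrees of freedom and an SD of 0.38. Separate cultures of a group were not measured, so the p-values rest on the spread between lines or media and not between replicate cultures. Overlaps were compared with the count of independent lists, the product of both list sizes over the number tested; the 2 lines' differences share no array.

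The fit was tested on simulated data with the real probe sets' means, in 20 draws. Each probe set's noise had the same spread on all 4 arrays. The real medium differences had an SD of 0.87 in T47D and 0.47 in ZR75-1. The rates below may therefore not hold for these data. For the shared medium effect, with 200 of 27307 probe sets changed per draw, 0.10%, 3.20%, 40.9% and 69.4% were recovered at log2 changes of 1, 2, 3 and 4, and 13.5% of the calls were false, above the nominal 5%. For the cell line difference, with 2000 changed, 3.93%, 62.3%, 95.2% and 98.9% were recovered and 6.49% of the calls were false.

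The choices, the rule for named probe sets and the alternatives were fixed before the data were examined, apart from the number of probe sets printed. The rule took, per direction, the probe sets with the largest difference in each line. It also took those ranked by the smaller of the lines' differences among probe sets that moved the same way or in opposite ways. Others were ranked by the smaller of the line differences in the media. The rule had set larger numbers per part. Only the leading 2 of each part are printed, a cut made after gene names were found missing. The 34 gene lists and the single genes fixed in advance could not be examined, since no table used here pairs the IDs with genes. For the same reason the set tests, the averaging of probe sets per gene and the agreement between probe sets of a gene were not run. Alternatives were no filter on dim probe sets, a stricter filter (mean of at least 4.82), no probe sets whose ID ends in _x_at or _s_at (designs that can bind several transcripts), quantile normalization, median centring and cyclic loess of the 4 arrays, thresholds of 1.5-fold and 3-fold, eBayes with a trend or robust, no block, and an adjusted p of 0.1. Figures were drawn with matplotlib version 3.10.9.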

Results

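Gene expression was measured in 2 human breast cancer cell lines that carry the oestrogen receptor, T47D and ZR75-1, after each had been made resistant to tamoxifen, a drug that binds this receptor and blocks its action in breast cells. Each line was adapted along 2 routes. In the TR cultures the cells had grown with 0.1 µM tamoxifen for 6 months. In the ODTR cultures they had first been held for 6 months in oestrogen-deprived medium, which holds charcoal-stripped serum and no phenol red, and tamoxifen was then added for a further 6 months. The design held 1 array for each line and route, 4 arrays in all, so no difference within a line had a replicate. Each array gave a log2 signal for 54675 probe sets. After 62 control probe sets had been set aside, the medians of the arrays lay between 2.69 (T47D ODTR) and 2.79 (T47D TR), and their upper quartiles between 4.73 and 4.90. Neither the deposited table nor the gene tables used here pair the probe set IDs with genes, so transcripts are given by probe set ID, with up to 2 IDs per direction, and only the array maker's control probe sets, whose IDs carry a name, are named.

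Among these named controls, GAPDH, the glycolytic enzyme often used as a loading reference, was 0.48 ± 0.05 higher on the log2 scale in T47D ODTR than in T47D TR (mean ± SD over n = 3 probe sets of the same arrays). In ZR75-1 the GAPDH difference was -0.02 ± 0.003 (SD, n = 3 probe sets). Actin, a cytoskeletal protein, was lower by a similar amount in both lines, with differences of -0.21 ± 0.14 in T47D and -0.18 ± 0.11 in ZR75-1 (SD, n = 3 probe sets each). These SDs describe agreement between probe sets and not between cultures.

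Controls of sample handling also differed between the arrays. The bacterial transcripts added to the RNA before labelling (poly-A spikes) averaged 7.21 in T47D TR, 6.61 in T47D ODTR, 5.57 in ZR75-1 ODTR and 4.91 in ZR75-1 TR over 12 probe sets. In the same order of arrays, the probe set for the 5′ part of 18S ribosomal RNA stood at 12.4, 12.1, 9.26 and 6.34, that for the middle part at 8.58, 9.34, 8.07 and 6.05, and that for the 3′ part at 7.50, 8.10, 8.08 and 8.07, so that the order of the spikes was shared by the 5′ probe set alone of the 3. The hybridisation spikes, added after labelling, differed by -1.04 ± 0.26 between ODTR and TR in ZR75-1 and by -0.19 ± 0.10 in T47D (SD, n = 9 probe sets). The gap between the 3′ and the 5′ probe set, which widens as RNA degrades, was 0.24 to 0.32 for GAPDH and 0.71 to 1.22 for actin across the 4 arrays. For the dap poly-A spike the gap was 2.32 in T47D TR, 2.39 in T47D ODTR, 3.08 in ZR75-1 ODTR and 3.81 in ZR75-1 TR. This spike is added and not the cells' own RNA, so its gap does not gauge how degraded the cells' RNA was. The bacterial control TrpnX, at the lower end of the scale, averaged 1.39 in T47D ODTR, 1.51 in T47D TR, 1.36 in ZR75-1 ODTR and 1.52 in ZR75-1 TR over 3 probe sets.

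**Figure D1:**
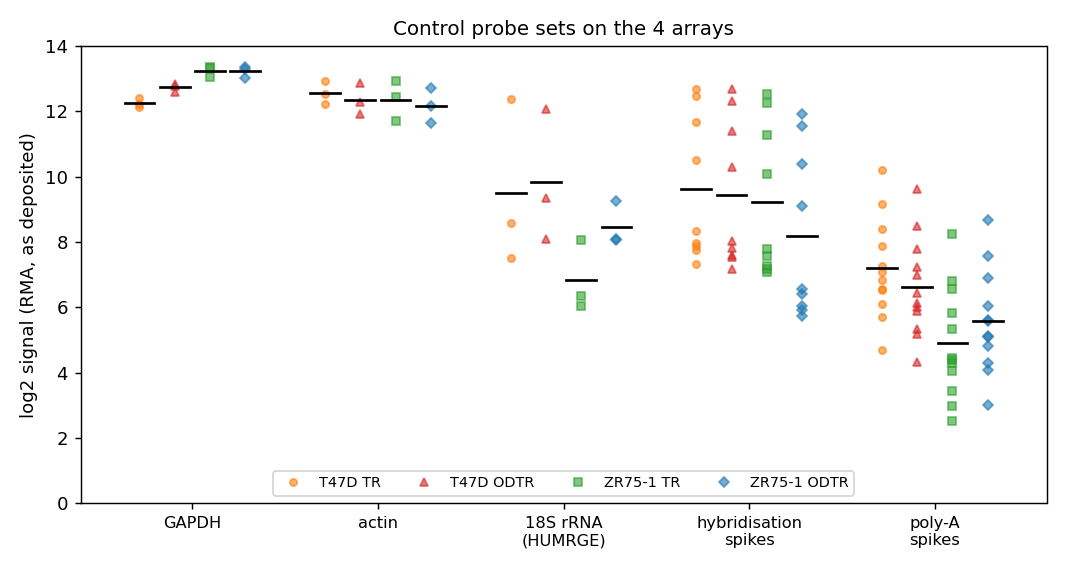
Log2 signal of control probe sets, as deposited, on the 4 arrays (1 array per cell line and medium); each point is a probe set and each black bar the mean over the probe sets of that control. The poly-A spikes averaged 7.21 and 6.61 in the T47D arrays and 4.91 and 5.57 in the ZR75-1 arrays, while actin lay between 12.2 and 12.6.

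In T47D, oestrogen deprivation before tamoxifen went with a broad difference in expression. Of the 27307 probe sets tested, 3601 were at least 2-fold higher in ODTR than in TR and 1986 at least 2-fold lower, 20.5% of the total. The difference reached at least 4-fold in 577 probe sets higher and 293 lower, and at least 16-fold in 41 higher and 19 lower. The largest positive difference was that of 209160_at, at 5.55 in TR and 12.2 in ODTR (6.64 on the log2 scale). The next was that of 215125_s_at, at 2.53 in TR and 8.28 in ODTR (5.75). The largest negative difference was that of 202833_s_at, at 8.70 in TR and 1.45 in ODTR (-7.25), followed by 209792_s_at, at 9.02 and 2.42 (-6.60). The ODTR value of 202833_s_at was close to that of TrpnX on the same array (1.39), so the size and rank of its difference depend on the lower end of the scale. The TR value of 215125_s_at and the ODTR value of 209792_s_at also lay below the medians of their arrays (2.79 and 2.69). With 1 array per medium these are differences between 2 arrays without a test. The split between higher and lower calls depended on scaling, with 64.5% of these probe sets higher as deposited, 72.5% after median centring and 55.2% after quantile normalization.

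In ZR75-1 the same change of medium went with fewer differences. Here 592 probe sets were at least 2-fold higher in ODTR and 482 at least 2-fold lower, 3.93% of those tested, and 65 and 40 reached 4-fold. The majority of higher over lower calls turned with scaling, from 55.1% higher as deposited to 48.8% after median centring, and with the threshold, to 49.4% at 1.5-fold. The probe set 217561_at stood at 4.43 in TR and 10.3 in ODTR (log2 difference 5.86) and 241031_at at 3.01 and 7.89 (4.88). The probe set 241367_at was lower in ODTR, at 3.89 against 8.28 (-4.39), as was 224710_at, at 3.78 against 7.74 (-3.96). The count of probe sets past 2-fold in T47D was 5.20 times that in ZR75-1, a ratio that was 2.65 at 1.5-fold and 8.10 at 3-fold. The SD of the difference over all tested probe sets was 0.87 in T47D and 0.47 in ZR75-1, and the correlation of the ODTR with the TR array was 0.913 and 0.974. The difference between the lines in the count was not tested, since neither line had a replicate.

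**Figure D2:**
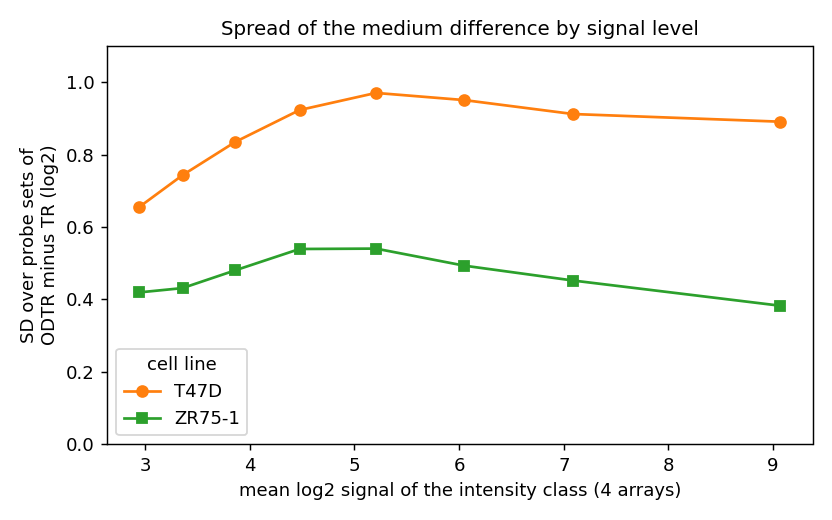
SD over probe sets of the log2 difference between ODTR and TR, in 8 classes of equal size ordered by mean log2 signal over the 4 arrays, for T47D (circles) and ZR75-1 (squares). The T47D spread was above the ZR75-1 spread in each class, 0.66 against 0.42 in the dimmest and 0.89 against 0.38 in the brightest.

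Whether a change of medium was common to both lines was tested with limma over the 4 arrays, with the cell line as a block and n = 2 lines per medium. No probe set passed an adjusted p of 0.05 in either direction, and the smallest adjusted p was 0.344, for 202917_s_at. That smallest value was 0.0737 with the stricter filter on dim probe sets, 0.169 after quantile normalization and 0.999 without a filter. At an unadjusted threshold of 0.05, 845 probe sets passed, against 1365 if p-values were spread evenly. The residual here is the difference between the lines in response, so a change in a single line raises the estimate and the residual together. The lower count therefore does not mean fewer changes than chance. With 200 of 27307 probe sets changed per simulated draw, the test recovered 69.4% at 16-fold in both lines and 40.9% at 8-fold. It recovered 3.20% at 4-fold and 0.10% at 2-fold, so common changes of 4-fold or less would mostly be missed if changes were that few. With 2000 changed, the same fit recovered 62.3% of 4-fold cell line differences and 3.93% of 2-fold ones. Detection at 4-fold thus depends on the number of probe sets changed, which is unknown here.

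A few probe sets, none past the test, still differed strongly in the same direction in both lines. The probe set 202917_s_at was 5.33 higher in ODTR in T47D and 4.83 higher in ZR75-1 on the log2 scale, a mean of 5.08 with a limma standard error of 0.36. The next, 203535_at, was 3.48 and 2.92 higher, with a mean of 3.20 and a standard error of 0.37. Both standard errors rest largely on the spread that limma pools over all probe sets, and neither measures variation between replicate cultures. In the other direction, 224710_at differed by -5.50 in T47D and -3.96 in ZR75-1, and 1555630_a_at by -5.71 and -3.63. The adjusted p from limma was 0.961 for each of 203535_at, 224710_at and 1555630_a_at.

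The differences in T47D and in ZR75-1 did not correlate across the tested probe sets, with Pearson's r = -0.01 and Spearman's rho = -0.004. Probe sets are not independent replicates, so these coefficients, and the overlap test and interval below, describe these arrays only. The p-value below counts probe sets and not cultures, so it overstates the evidence. In all, 384 probe sets differed at least 2-fold in both lines, where independent lists would share 220 (odds ratio 2.25, p = 2.69e-32, two-sided Fisher's exact test across probe sets). Of these, 109 were higher in both lines and 75 lower in both, against 78.1 and 35.1 for independent lists. A further 130 were higher in T47D and lower in ZR75-1 and 70 the reverse, against 63.6 and 43.1. The same direction was thus seen in 184 of 384, or 47.9% (95% exact binomial interval 42.8% to 53%). The signed difference between the lines in their response was at least 2-fold for 7007 probe sets. The value was greater (more positive) in T47D for 4292 and in ZR75-1 for 2715. A probe set that fell in T47D and stayed level in ZR75-1 thus counts as greater in ZR75-1, so these counts do not show which line responded more.

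**Figure D3:**
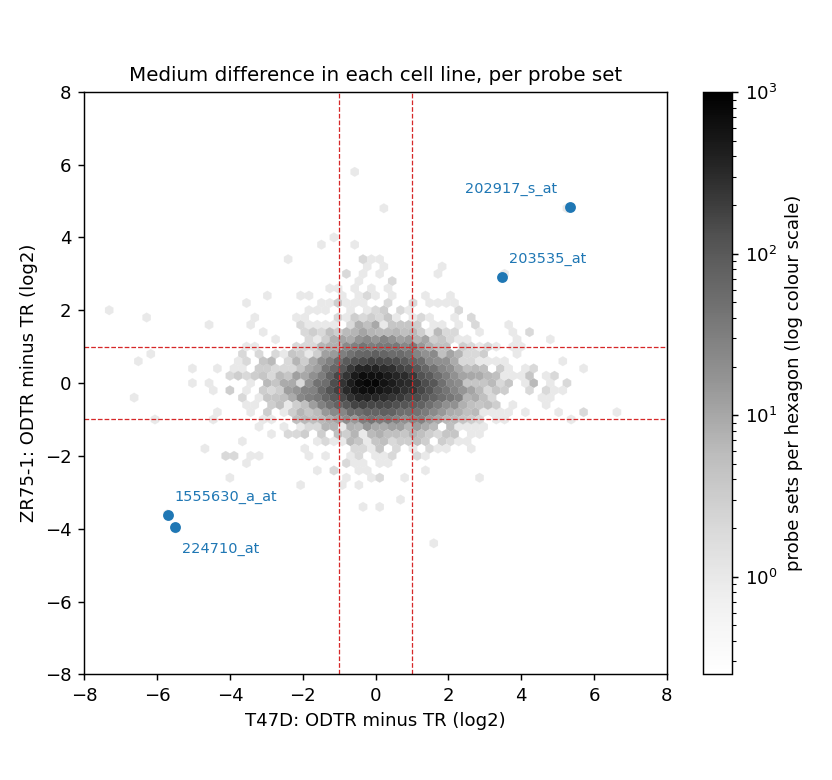
Log2 difference between ODTR and TR in T47D (horizontal) and ZR75-1 (vertical) for the 27307 tested probe sets, as counts per hexagon on a log colour scale; dashed lines mark 2-fold and the 4 labelled points are the probe sets with the largest differences in the same direction in both lines. The cloud is wider along T47D (SD 0.87) than along ZR75-1 (SD 0.47).

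The cell lines differed from each other in both media. In limma with the medium as a block (n = 2 arrays per line, of different media), 294 probe sets were higher in T47D and 374 higher in ZR75-1 at an adjusted p of 0.05. The T47D-high probe set 201348_at stood at 9.26 and 9.71 in the T47D arrays (TR and ODTR) and at 1.58 in each ZR75-1 array, and 231736_x_at at 10.3 and 11.6 against 2.41 and 3.40. The ZR75-1-high probe set 205009_at stood at 11.4 and 12.2 in the ZR75-1 arrays and at 3.65 and 3.03 in the T47D arrays, and 206378_at at 8.61 and 9.55 against 1.94 and 1.71. The ZR75-1 values of 201348_at and the T47D values of 206378_at lay near the level of TrpnX, so the sizes of these differences depend on the lower end of the scale. Each of these 4 had a limma adjusted p of 0.00651, with mean log2 differences (T47D minus ZR75-1) of 7.90, 8.03, -8.48 and -7.25.

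By size alone, 1207 probe sets were at least 2-fold higher in T47D in both media and 1572 at least 2-fold higher in ZR75-1 in both. A further 241 differed by at least 2-fold in opposite directions in the 2 media. The line differences measured in TR and in ODTR correlated across probe sets at r = 0.555. The count called by limma depended on scaling, falling from 668 to 137 after median centring, and on the filter, with 78 when dim probe sets were kept. The poly-A spikes differed between the lines in the same arrays, by 2.29 ± 0.53 in TR and 1.05 ± 0.23 in ODTR (SD, n = 12 probe sets).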

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

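Several tests of explanations were chosen after the results were seen. They cover intensity classes, mixed or other RNA, the share moving the same way, and the count without _x_at and _s_at probe sets. The rule that names the probe sets below, and the counting per direction, were fixed before. Only the cut to the leading 2 probe sets per direction came later. In these probe sets the lines differed in opposite directions by more than 2-fold, and the difference between the lines was not tested for any of them, since each rests on 4 single arrays. The probe set 213564_x_at differed by 2.90 between ODTR and TR in T47D and by -2.55 in ZR75-1, a difference between the lines of 5.45 on the log2 scale. For 204162_at the values were 1.93 in T47D and -1.73 in ZR75-1, a difference of 3.65. In the other direction, 204607_at differed by -2.92 in T47D and 2.46 in ZR75-1 (-5.39 between the lines), and 206509_at by -2.34 and 3.37 (-5.71).

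The medium difference was larger in T47D than in ZR75-1, with 5587 against 1074 probe sets at 2-fold. Noise of dim probe sets is argued against as the whole cause, since the SD in T47D was 2.33 times that in ZR75-1 in the brightest of 8 intensity classes and 1.56 times in the dimmest; ZR75-1 RNA mixed into the T47D ODTR array at 5% or more is argued against too, since 35 probe sets bright in both ZR75-1 arrays (at least 7) and dim in T47D TR (at most 3.5) changed by a median of 0.10 (quartiles -0.36 and 0.67), where such a share would add 1.41. Whether the T47D ODTR array holds RNA of another line or of a much diverged culture could not be settled: 26 of 45 probe sets bright in T47D TR and dim in both ZR75-1 arrays stayed bright (57.8%) and 4 turned dim, against 28 and 0 of 32 in the mirrored comparison in ZR75-1. T47D ODTR correlated with T47D TR at 0.913 and with the ZR75-1 arrays at 0.865 and 0.874, which goes with a T47D origin, but no other line was at hand to show what unrelated lines would keep. A stronger response of T47D to the medium stays open, untested. It cannot be told apart from a difference between single cultures, or between single arrays in labelling and hybridisation.

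More probe sets changed in both lines than independent lists give, in each of the 4 combinations of directions. A response in the same direction does not account for the excess as a whole, since 47.9% moved the same way (interval 42.8% to 53%). Shared intensity does not either. The observed count was still 1.67 times the expected one within intensity classes (95% Poisson interval 1.51 to 1.84, counting error only). Nor do probe sets with an ID ending in _x_at or _s_at, with a ratio of 1.80 without them (1.58 to 2.05). Other probe sets that may bind several transcripts were kept, so they are not covered. The size of the excess depended on the threshold and the filter: the plain ratio was 1.75 at 2-fold, 1.17 at 1.5-fold, 3.87 at 3-fold and 2.86 without a filter. What stays open is that some transcripts, or some probe sets, may vary more than others between any pair of arrays, which replicate arrays would be needed to test.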

How the results depend on the processing

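The 179 values of named probe sets under the filters and scalings kept their direction and their side of 2-fold, except where a filter removed the probe set (10 cases). A filter leaves the value of a kept probe set unchanged by construction, so only the scalings could move these values. The named probe sets were also chosen for large differences, so their agreement says little about probe sets near 2-fold. The limma test of the shared medium effect called no probe set under any alternative run, eBayes with a trend or robust, no replicate block and an adjusted p of 0.1 included; its smallest adjusted p ranged from 0.0737 (stricter filter) to 1 (no block). The count for the cell line difference, 668, became 78 without a filter, 137 after median centring and 1595 at an adjusted p of 0.1, and lay between 512 and 942 otherwise; the cause was not tested, and 823 were called without the block. Counts moved with the number of probe sets or the threshold by construction, in the order T47D higher, T47D lower, ZR75-1 higher, ZR75-1 lower, both lines the same way, both lines in opposite ways, response differing between the lines, and cell line difference in both media. With the stricter filter they were 2292, 1240, 278, 257, 116, 113, 4040 and 1689, without _x_at and _s_at probe sets 1958, 1239, 369, 298, 106, 128, 4090 and 1694, at 1.5-fold 6671, 5079, 2190, 2242, 1091, 1145, 13272 and 5683, and at 3-fold 1215, 574, 129, 92, 32, 24, 2708 and 1126. The correlation of the lines' responses was 0.047 with the stricter filter and between -0.02 and 0.002 elsewhere. The ratio of changed probe sets, T47D over ZR75-1, ranged from 2.65 at 1.5-fold to 8.10 at 3-fold and was 5.16 after cyclic loess. No paired analysis by replicate number was possible because the labels give no replicate numbers, and leaving out an array left the additive fit no residual degree of freedom, so those fits gave no test; leaving out a line leaves the other line's difference as reported. Averaging probe sets per gene, and the alternatives for gene lists, were not run, for want of gene names. Without detection calls the background of each probe set is unknown; the TrpnX control averaged 1.36 to 1.52, and differences against values near that level depend on the lower end of the scale.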

Other observations

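The lines did not stand closer together after oestrogen deprivation than without it. The T47D and ZR75-1 arrays correlated at 0.880 in TR and 0.865 in ODTR over the tested probe sets. In TR, 2503 probe sets were at least 2-fold higher in T47D and 3945 higher in ZR75-1, while in ODTR the counts were 3505 and 3010. None of these values was tested, as each is from a single array per line. The balance of these counts was not examined under other scalings, which moved the T47D split between higher and lower calls.

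The probe sets that changed most in both lines seemed to move the same way, as a hypothesis noticed in the data and tested afterwards on the same data. Of those changed at least 4-fold in both lines, 12 of 18 moved the same way, or 66.7% (95% exact binomial interval 41.0% to 86.7%), against 47.9% at 2-fold and 32 of 56 at 3-fold. At 8-fold there were 3, all in the same direction. These include 224710_at and 1555630_a_at, whose values were alike on the T47D ODTR, T47D TR, ZR75-1 ODTR and ZR75-1 TR arrays. They stood at 3.19, 8.69, 3.78 and 7.74 and at 2.62, 8.33, 3.72 and 7.34. Several probe sets can measure the same transcript, which could not be checked without gene names. The intervals and tests here count probe sets as independent and may overstate the evidence. At 2-, 3- and 4-fold the share did not pass an exact binomial test against equal shares (adjusted p = 0.444 at each, over 4 thresholds); at 8-fold, 3 probe sets cannot give a two-sided p below 0.25, so that threshold could not pass. Equal shares are not exactly what independent lists give. Both lines had more higher than lower calls at 2-, 3- and 4-fold, which alone makes the same direction slightly more frequent. At 4-fold the interval leaves both a shared direction and no relation open.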
